A study of Mus musculus with 105 samples.

How the data were processed

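Tissue was whole striatum, midbrain or brainstem of the injected side of the brain, taken from Gpnmb wild-type (WT) or knockout (KO) mice of both sexes 60 or 90 days after preformed fibrils (PFF) or monomer of alpha-synuclein, per the series text. RNA was extracted with the RNeasy Lipid Tissue kit with on-column DNase digestion, per the labels' protocols, and the molecule is given as polyA RNA. Library kit, strandedness, read length and injection site are not given in the sources used here. Reads were aligned with GSNAP to GRCm38, per the submitters' processing notes, and the version of GSNAP is not given in the sources used here. The deposited tables hold a count of reads that align uniquely to each gene model, per the file headers, and a normalized RPKM adjusted by a size factor of each library, per the file headers. The deposited RPKM values were not used here for any test.

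All 35 libraries of each of the 3 regions were used. Genotype, region, treatment, day and sex were taken from the labels, which gave 18 groups of 5 to 7 libraries. The labels do not tie libraries of different regions to animals and do not say that replicates of a group came from separate animals, so p-values measure only the spread between these samples. Replicate numbers were assigned here within each group and mark no pairing. The tables list 52636 Ensembl gene identifiers and no total or unassigned category. Symbols and coordinates of GENCODE M21, on GRCm38, were found for 52403 of them, and the other 233 kept their identifier. Total counts ran from 19558043 to 41663139 in the striatum, from 19036830 to 33499345 in the midbrain and from 20125274 to 43816924 in the brainstem. Counting intervals and floors, given for Gpnmb in KO, cover counting error only, because PCR copies cannot be told from independent molecules here. Without strand information, reads from a gene and from an overlapping or antisense gene cannot be separated, and unique alignment leaves out reads that near-identical copies share.

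Each region was fitted on its own with edgeR 4.0.16 in R: filterByExpr on the 6 groups with its default minimum count of 10, TMM normalization, a negative binomial model with a term for each group and for sex, robust quasi-likelihood dispersions and glmQLFTest. The groups of a region shared 1 estimate of the spread. The filter kept 18636 genes in the striatum, 19110 in the midbrain and 19119 in the brainstem. The comparisons were PFF against monomer at day 90 with genotypes averaged, in WT and in KO, the genotype by treatment interaction at day 90, KO against WT with conditions averaged and in each of the 3 conditions, and PFF day 90 against PFF day 60 with genotypes averaged, 9 in each region. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the region, and every adjusted p of a gene is from edgeR unless DESeq2 is named. The difference of the PFF response between regions came from 1 fit of all libraries.

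Genes are named by a rule: Gpnmb always, up to 8 genes per direction with the smallest adjusted p for the genotype-averaged PFF, condition-averaged genotype and time comparisons, up to 3 for the others, and up to 4 members of a gene list. Only genes with a symbol are named, and predicted models are counted and not named unless the text says otherwise. Some genes that the rule names are not reported here. The rule, the comparisons, the gene lists, the main model and the first group of other settings below were chosen before the data were examined.

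The 33 fixed lists cover disease-associated and homeostatic microglia, complement, reactive and general astrocytes, type I interferon response, MHC class I and class II presentation, T cells, border-associated macrophages, dopaminergic, striatal projection, cholinergic and monoaminergic hindbrain, cortical, cerebellar, thalamic and pan-neuronal markers, hindbrain Hox genes, myelinating oligodendrocytes and their precursors, endothelial, mural, ependymal, choroid plexus and meningeal fibroblast cells, erythrocytes, lysosome, Parkinson disease genes, unfolded protein and integrated stress response, heat shock proteins, immediate early genes, the melanosome and MITF family and the chromosome 6 neighbours of Gpnmb. They were written from general knowledge of marker genes. They hold 408 genes, of which 7 stand on more than 1 list, such as Trem2. Lists with at least 4 tested genes were tested with camera in limma 3.58.1 on voom weights, with a preset inter-gene correlation of 0.01 and adjustment over all lists and 6 comparisons of a region. Camera compares a list with all other genes. Its calls were set against those with a correlation estimated for each list, which treats members that vary together as fewer independent genes, and against fry, which asks only whether the genes of a list move, on balance, one way. A library's score on a list is the mean log2 CPM (prior count of 2) of its members, centred on the regional mean.

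The length slope is the slope of a library's log2 CPM, relative to the regional mean, on the log2 of summed exon length, over protein-coding genes with a mean log2 CPM above 3. Libraries below -0.25 are called low-slope.

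The first group of other settings was RLE size factors in place of TMM, DESeq2 1.42.0 with the same design, no low-count filter, no sex term, a fit of only the groups compared, and leaving out each library in turn. Added after the data were seen were fits without the low-slope libraries, with the length slope as a covariate, and with the choroid plexus, cerebellar and cortical neuron scores as covariates, called dissection scores. So were the estimated correlation within these fits, 3 further gene lists, the -0.25 limit, and the choice of patterns weighed. The thalamic neuron score was used for the myelin score alone. Chance was tested with 50 splits per region for each of 3 schemes, exchanging treatment, genotype or day between libraries, the real one included. Gpnmb was left out of the counts when genotype was exchanged.

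The procedure was tested on simulated counts drawn from the real means and library sizes with 200 changed genes. For the genotype-averaged PFF comparison it recovered 78%, 98% and 84% of genes changed 2-fold in the striatum, midbrain and brainstem, and for the condition-averaged genotype comparison 88%, 96% and 92%. Genes were drawn independently, and a list raised 1.3-fold was called in every simulated run. In every library the sex label matched the larger of the Xist and Ddx3y counts. Of 261 pairs of libraries in the same group, the lowest chi-square per gene was 4.63, where repeated draws from 1 library would give about 1.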

Results

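RNA was sequenced from ipsilateral striatum, midbrain or brainstem of mice of both sexes that carried (WT) or lacked (KO) Gpnmb. The gene encodes a transmembrane glycoprotein of phagocytes and pigment cells. The animals had received preformed fibrils of alpha-synuclein (PFF), an aggregated form that seeds aggregation of the endogenous protein, or alpha-synuclein monomer, which served as the control. Tissue was collected 60 or 90 days later, and the series asks how Gpnmb takes part in the response to the spreading pathology. Each region had 35 libraries in 6 groups: WT monomer day 90 (n = 5), WT PFF day 60 (n = 7), WT PFF day 90 (n = 5), KO monomer day 90 (n = 6), KO PFF day 60 (n = 5) and KO PFF day 90 (n = 7). Total counts per library ran from 19036830 to 43816924 with a median of 26803231. Between 23738 and 26081 gene models had at least 1 read. No monomer group at day 60 was analysed here, so time after injection, age and cohort are not separated in comparisons of the 2 days.

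Gpnmb (ENSMUSG00000029816; GRCm38 chromosome 6, 49036546 to 49070929, plus strand, protein coding) was nearly absent from the KO libraries and rose with PFF in WT. Over all KO libraries pooled it had 14 reads in the striatum (n = 18), 9 in the midbrain (n = 18) and 3 in the brainstem (n = 18), against 2723, 11638 and 34197 reads in WT (n = 17 each). Relative to total counts, WT exceeded KO 246-fold in the striatum (95% counting interval 147 to 451), 1360-fold in the midbrain (718 to 2980) and 11200-fold in the brainstem (3850 to 54500). In the brainstem PFF day 60 groups the KO libraries held 0 reads, so WT was at least 1020-fold higher, taking 3 counts over the group as the floor, and the lower limit of the two-sided 95% interval was 832. In WT striatum Gpnmb stood at 2.74 ± 0.349 CPM (SD, n = 5) after monomer, 7.27 ± 2.28 CPM (n = 7) at PFF day 60 and 9.56 ± 5.41 CPM (n = 5) at PFF day 90. In WT midbrain these levels were 2.85 ± 0.546, 11.1 ± 7.66 and 75.6 ± 33.5 CPM, and in WT brainstem 4.42 ± 1.40, 20.6 ± 18.5 and 195 ± 84.4 CPM. The day 90 rise over monomer in WT was log2 1.80 ± 0.33 in the striatum (edgeR adjusted p = 0.00177), 4.70 ± 0.37 in the midbrain (adjusted p = 1.78e-10) and 5.51 ± 0.44 in the brainstem (adjusted p = 1.55e-10). Fitted genotype-averaged or interaction folds of Gpnmb are not given, because in KO they rest on single reads.

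**Figure D1:**
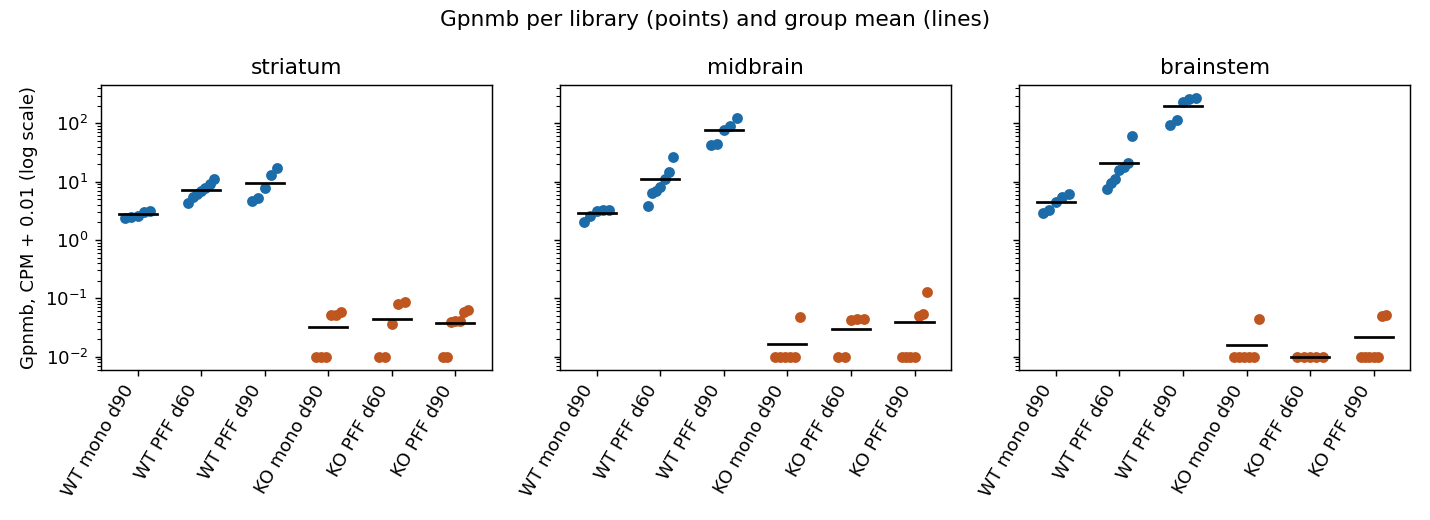
Gpnmb in each library (points) as CPM plus 0.01 on a log axis, by region and group, with group means as lines; WT is blue and KO is orange. WT libraries rise from monomer to PFF day 90, to a mean of 195 CPM in the brainstem, while KO libraries sit at or near 0 in every region.

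The first comparison asks what PFF changes relative to monomer at day 90, averaged over both genotypes (12 PFF and 11 monomer libraries per region). In the striatum Clec7a, a pattern recognition receptor (29.3-fold, log2 4.88 ± 0.43), and Cst7, a cystatin of activated microglia (60.6-fold, log2 5.92 ± 0.57), were higher. So were Mmp12, the macrophage metalloelastase (35.5-fold, log2 5.15 ± 0.47) and Itgax, which encodes CD11c (20.1-fold, log2 4.33 ± 0.44). The lymphocyte receptor gene Ly9 (7.95-fold, log2 2.99 ± 0.27), the chemokine genes Ccl3 (6.8-fold, log2 2.77 ± 0.27) and Ccl12 (6.6-fold, log2 2.72 ± 0.27) rose with them. So did the complement gene C4b (4.7-fold, log2 2.23 ± 0.22) and Gfap, an intermediate filament of astrocytes (4.39-fold, log2 2.13 ± 0.21). Values after ± on log2 changes are standard errors throughout. The genes with the smallest adjusted p among those that fell were the transcription factor genes Pou3f1 (log2 -0.59 ± 0.099), Foxo6 (-0.76 ± 0.13), Sox8 (-0.34 ± 0.068) and Sp9 (-0.55 ± 0.12). With them fell the adaptor gene Shb (-0.45 ± 0.087), Lrrn2 (-0.33 ± 0.066), Fam222a (-0.46 ± 0.099) and Slc32a1, the vesicular GABA transporter (-0.56 ± 0.12). With edgeR 810 of 18636 genes passed, 668 higher and 142 lower. The count was 2295 (1443 higher, 852 lower) without the 4 striatal libraries with a low length slope, in which long genes were under-represented, and 2110 (1097 higher, 1013 lower) with the length slope as a covariate. It was 1990 without KO PFF day 90 replicate 1, one of those 4 libraries. DESeq2 called 1084, 777 higher and 307 lower.

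Among the gene lists fixed beforehand, all 21 tested genes of the type I interferon response rose in the striatum (median log2 1.93). Oasl2 (2.33 ± 0.25), Ifit1 (2.14 ± 0.24), Ifit3 (1.93 ± 0.23) and Irf7, a regulator of interferon genes (2.12 ± 0.25), were among them. Disease-associated microglia genes had 15 of 18 higher (median 1.06), homeostatic microglia genes 14 of 16 (0.51), complement genes 10 of 11 (1.22), reactive astrocyte genes 11 of 13 (1.29) and MHC class I presentation 10 of 11 (1.11). Adjusted over the list alone the counts of these 6 lists were 21, 15, 14, 10, 12 and 11. Examples were Trem2, a microglial lipid receptor (1.06 ± 0.18), C3ar1, the receptor of complement C3a (2.04 ± 0.21), Serpina3n, a protease inhibitor of reactive astrocytes (2.52 ± 0.29), and B2m, the MHC class I light chain (1.5 ± 0.18). Border-associated macrophage genes had 4 of 8 higher, 5 adjusted over the list alone (median 0.53), and general astrocyte genes 3 of 12 higher, 4 adjusted over the list alone (median 0.17). These 8 lists passed limma camera with an estimated correlation as well, at adjusted p between 0.00611 and 0.0278. With the length slope as a covariate 0 of the 8 held in that test (adjusted p 0.0573 to 0.0834), and without the low-slope libraries 2 did, homeostatic microglia and complement (0.0356 to 0.0638 over the 8). All 8 passed in both fits with the preset correlation and with fry.

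Other striatal lists passed camera only with its preset correlation, and the adjusted p given is that with an estimated one. The lysosome list had 9 higher and 0 lower of 19, 11 and 2 adjusted over the list alone, including Laptm5 (0.79 ± 0.10), Grn, which encodes progranulin (0.79 ± 0.13), and Ctsd, which encodes cathepsin D (0.77 ± 0.17), and an adjusted p = 0.142. Markers of striatal projection neurons had 4 of 16 lower, 6 adjusted over the list alone (median -0.18, adjusted p = 0.274). Those with the smallest p were Gpr6 (-0.54 ± 0.14), Syndig1l (-0.33 ± 0.089), the adenosine receptor gene Adora2a (-0.33 ± 0.093) and the adenylyl cyclase gene Adcy5 (-0.35 ± 0.10). They passed in 23, 19, 12 and 7 of 23 fits that left out 1 library. MHC class II genes had 1 of 6 higher, 4 adjusted over the list alone (median 0.57, adjusted p = 0.433). Immediate early genes had 0 of 12 lower, 1 adjusted over the list alone (median -0.39, adjusted p = 0.561), and choroid plexus genes 0 of 10 lower, 0 adjusted over the list alone (median -0.79, adjusted p = 0.694). The choroid plexus score varied between striatal libraries from -2.97 to 2.98 on the log2 scale.

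In the midbrain the chemokine genes Ccl4 (42-fold, log2 5.39 ± 0.23) and Ccl3 (36.6-fold, log2 5.20 ± 0.25) had the smallest adjusted p. They were followed by the transporter gene Slc15a3 (10.1-fold, log2 3.34 ± 0.16), Dock2, a regulator of leukocyte migration (4.29-fold, log2 2.10 ± 0.10), and Cd52 (21.1-fold, log2 4.4 ± 0.21). Next came the myeloid transcription factor gene Irf8 (5.57-fold, log2 2.48 ± 0.12), the innate receptor gene Tlr2 (6.15-fold, log2 2.62 ± 0.13) and Plek, which encodes pleckstrin (3.74-fold, log2 1.90 ± 0.097). Among genes that fell were Atp1b1, a sodium pump subunit (log2 -0.35 ± 0.027), Snap25, a synaptic fusion protein (-0.39 ± 0.032), Tuba4a (-0.39 ± 0.034) and Dync1i1, a dynein chain of neurons (-0.33 ± 0.028). Nap1l2 (-0.38 ± 0.034), the neurofilament gene Nefl (-0.43 ± 0.040), Cadps, which primes vesicles for release (-0.31 ± 0.030), and Mdh1 (-0.29 ± 0.028) fell as well. With edgeR 5963 of 19110 genes passed, 3277 higher and 2686 lower.

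Among midbrain lists, all 18 disease-associated microglia genes rose (median log2 2.89), with Clec7a at 5.85 ± 0.30, Trem2 at 2.85 ± 0.15 and the phagocyte marker Cd68 at 3.26 ± 0.17. All 16 homeostatic microglia genes (median 1.19), all 11 complement genes (median 2.61) and all 13 reactive astrocyte genes (median 1.82) rose too. So did all 21 interferon genes (median 2.56) and all 11 MHC class I genes (median 1.64). Adjusted over the list alone the counts were 18, 16, 11, 13, 21 and 11. Examples were Csf1r, the receptor that maintains microglia (1.21 ± 0.078), C1qc (2.73 ± 0.15), Timp1 (3.65 ± 0.20), Mx1 (3.58 ± 0.25) and the peptide transporter gene Tap1 (1.62 ± 0.12). Lysosome genes had 16 of 19 higher, 16 adjusted over the list alone (median 0.39), with Ctsd at 2.14 ± 0.13 and Grn at 1.95 ± 0.12. Pan-neuronal genes had 13 of 14 lower, 13 adjusted over the list alone (median -0.29), with Nefm at -0.62 ± 0.066 and Stmn2 at -0.34 ± 0.035. Adjusted p with an estimated correlation lay between 0.0202 (pan-neuronal) and 0.0495 (lysosome) for these 8 lists.

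Other midbrain lists are given with the adjusted p under an estimated correlation. Dopaminergic markers of the midbrain had 1 higher and 7 lower of 14, 1 and 9 adjusted over the list alone (median -0.40, adjusted p = 0.393). Th, the rate-limiting enzyme of dopamine synthesis (-0.50 ± 0.11), the dopamine transporter gene Slc6a3 (-0.65 ± 0.13), Ret (-0.42 ± 0.071) and Chrna6 (-0.45 ± 0.093) were lower. The cholinergic and monoaminergic list had 1 higher and 5 lower of 11, 1 and 6 adjusted over the list alone (median -0.68, adjusted p = 0.618), with the cholinergic genes Chat at -0.78 ± 0.15 and Slc5a7 at -0.76 ± 0.14. General astrocyte genes had 8 of 12 higher, 8 adjusted over the list alone (median 0.23, adjusted p = 0.0534), led by the water channel gene Aqp4 (1.17 ± 0.075). Higher were 8 of 8 border-associated macrophage genes (median 0.70, adjusted p = 0.317), 6 of 7 MHC class II genes (median 1.07, adjusted p = 0.317), 6 of 10 T cell genes (median 0.48, adjusted p = 0.333) and 4 of 9 meningeal fibroblast genes (median 0.32, adjusted p = 0.633), with 8, 7, 6 and 6 adjusted over the list alone. Hindbrain Hox genes, which mark tissue behind the midbrain, had 6 of 10 lower, 8 adjusted over the list alone (median -0.51, adjusted p = 0.451). Parkinson disease genes had 1 higher and 7 lower of 15, 1 and 8 adjusted over the list alone (median -0.10, adjusted p = 0.12).

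In the brainstem Tent5c, a noncanonical poly(A) polymerase gene (8.33-fold, log2 3.06 ± 0.14), and Lgals3bp, a galectin binding protein (8.69-fold, log2 3.12 ± 0.14), were among the genes that rose. So were Cd84 (16.4-fold, log2 4.03 ± 0.19) and Ccl3 (44.8-fold, log2 5.48 ± 0.26). Irf8 (7.43-fold, log2 2.89 ± 0.14), Tlr2 (7.97-fold, log2 2.99 ± 0.15), Plek (6.09-fold, log2 2.61 ± 0.13) and C3ar1 (14.5-fold, log2 3.86 ± 0.19) followed by adjusted p. Among those that fell were Klhdc2 (log2 -0.42 ± 0.038), Dync1i1 (-0.57 ± 0.053), Gnaz (-0.54 ± 0.052), Lgr6 (-0.81 ± 0.080), Lrfn5 (-0.45 ± 0.046) and the neuronal tubulin gene Tubb3 (-0.85 ± 0.087). Insig1, a regulator of sterol metabolism (-0.69 ± 0.072), fell as well. With edgeR 7258 of 19119 genes passed, 3586 higher and 3672 lower.

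In the brainstem all 18 disease-associated microglia genes (median log2 2.93), all 16 homeostatic microglia genes (median 1.64), all 14 reactive astrocyte genes (median 2.43) and all 21 interferon genes (median 3.06) rose. So did all 11 MHC class I genes (median 1.94) and 10 of 11 complement genes (median 2.89). Adjusted over the list alone these 6 counts were 18, 16, 14, 21, 11 and 10. Itgax (6.53 ± 0.34), Clec7a (6.10 ± 0.31), the chemokine gene Cxcl10 (5.93 ± 0.36), Timp1 (5.20 ± 0.31) and Osmr, a cytokine receptor of reactive astrocytes (2.71 ± 0.14), were among them. Lysosome genes had 14 higher and 2 lower of 19, 14 and 2 adjusted over the list alone (median 0.58), with Laptm5 at 2.54 ± 0.13 and Grn at 2.49 ± 0.15. Pan-neuronal genes had 12 of 14 lower, 12 adjusted over the list alone (median -0.42), with Nefl at -0.72 ± 0.075 and Snap25 at -0.44 ± 0.054. With an estimated correlation the adjusted p was 0.0215 for the interferon, microglia, complement, reactive astrocyte and lysosome lists, but 0.0512 for MHC class I and 0.0803 for pan-neuronal genes, for which the call was lost. Of the 7 brainstem lists called in that test, Parkinson disease genes included, 0 held with the length slope as a covariate (adjusted p 0.0847 to 0.194) or without the low-slope libraries (0.0746 to 0.12). All 7 passed in both fits with the preset correlation and fry. With the dissection scores 6 held, and Parkinson disease genes did not (adjusted p = 0.0754).

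Other brainstem lists are given in the same way. Parkinson disease genes had 1 higher and 9 lower of 15, 1 and 10 adjusted over the list alone (median -0.28, adjusted p = 0.0488). Sncb, which encodes beta-synuclein (-0.63 ± 0.087), Uchl1 (-0.73 ± 0.15) and Atp13a2 (-0.54 ± 0.089) fell. T cell genes had 6 of 10 higher, 7 adjusted over the list alone (median 2.0, adjusted p = 0.333), with Ccl5, also made by other cells, at 4.67 ± 0.33, Cd5 at 1.96 ± 0.25 and Cd8a at 3.03 ± 0.60. Higher were 8 of 12 general astrocyte genes (median 0.41, adjusted p = 0.0803), 5 of 8 border-associated macrophage genes (median 0.62, adjusted p = 0.294) and 4 of 7 MHC class II genes (median 0.75, adjusted p = 0.543), with 8, 5 and 4 adjusted over the list alone. The striatal projection neuron list, which is foreign to this tissue, had 8 of 16 lower, 8 adjusted over the list alone (median -0.22, adjusted p = 0.285). The other 13 lists passed in no region in this comparison: cortical, cerebellar and thalamic neurons, myelinating oligodendrocytes, oligodendrocyte precursors, endothelial, mural and ependymal cells, erythrocytes, the unfolded protein and integrated stress response, heat shock proteins, the melanosome and MITF family, and the chromosome 6 neighbours of Gpnmb. Their lowest adjusted p with the preset correlation was 0.0703, for the endothelial list in the midbrain. Single members still moved in the brainstem, such as the transcription factor gene Atf3 of the stress response (3.17 ± 0.18) and the melanosomal gene Pmel (0.96 ± 0.14). Of the immediate early genes, a list that passed in the striatum only, Egr2 rose in the brainstem (3.73 ± 0.21).

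**Figure D2:**
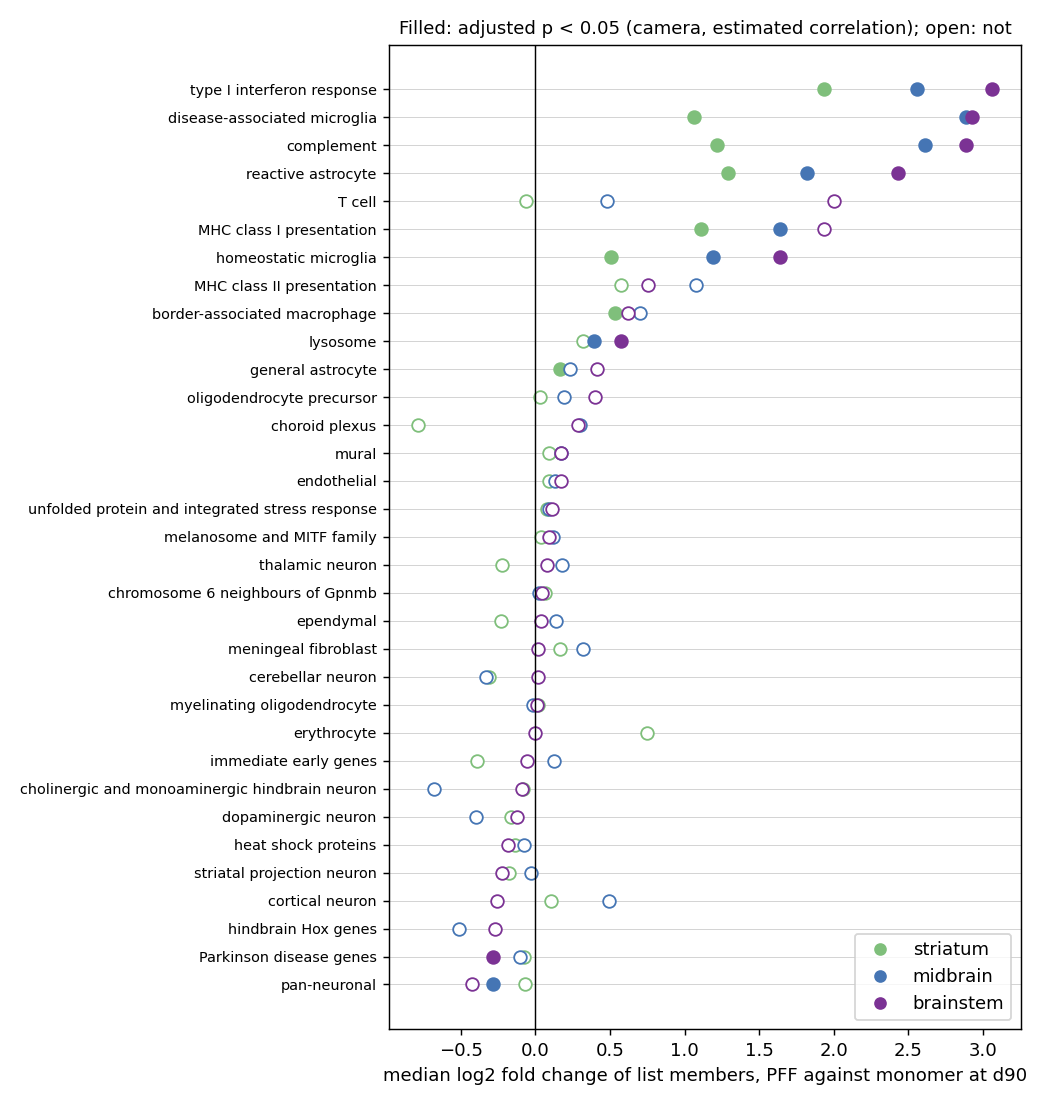
Median log2 fold change of the tested members of each fixed gene list, PFF against monomer at day 90 with genotypes averaged, in the 3 regions (12 PFF and 11 monomer libraries each); filled points passed camera with an estimated correlation and open points did not. Interferon, complement, microglia and reactive astrocyte lists lie to the right, and pan-neuronal genes to the left, at -0.42 in the brainstem.

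The response to PFF at day 90 was then taken in each genotype (5 PFF and 5 monomer libraries in WT, 7 and 6 in KO), to ask whether loss of Gpnmb alters it. In the striatum of WT mice Mmp12 (53.5-fold, log2 5.74 ± 0.75), Gbp3, an interferon-induced GTPase (4.54-fold, log2 2.18 ± 0.28), and Clec7a (24-fold, log2 4.58 ± 0.63) rose with the smallest adjusted p. Cfap157 (log2 -1.23 ± 0.28), Shb (-0.58 ± 0.13) and Fbln7 (-0.78 ± 0.18) fell. In KO striatum these places were held by Clec7a (35.9-fold, log2 5.17 ± 0.59), Gfap (5.23-fold, log2 2.39 ± 0.28) and Ly9 (8.42-fold, log2 3.07 ± 0.37) among rises, and by Hip1r (-0.35 ± 0.072), Foxo6 (-0.78 ± 0.17) and Pou3f1 (-0.57 ± 0.13) among falls. In the midbrain Ccl4 rose 32.5-fold in WT (log2 5.02 ± 0.33) and 54.4-fold in KO (5.76 ± 0.32), and Ccl3 by log2 4.94 ± 0.36 and 5.45 ± 0.34. Cd52 in WT (4.32 ± 0.31) and Slc15a3 in KO (3.48 ± 0.21) came next. Snap25 (-0.37 ± 0.048 in WT, -0.40 ± 0.042 in KO) and Atp1b1 (-0.30 ± 0.041 and -0.40 ± 0.035) fell in both, with Tuba4a in WT (-0.37 ± 0.051) and Dync1i1 in KO (-0.39 ± 0.037). In the brainstem Tent5c (3.23 ± 0.20 in WT, 2.89 ± 0.18 in KO) and Lgals3bp (3.16 ± 0.21 and 3.08 ± 0.19) rose in both, with Ccl3 in WT (5.83 ± 0.39) and Cd84 in KO (4.19 ± 0.26). Klhdc2 fell in both (-0.44 ± 0.058 and -0.40 ± 0.051), Dync1i1 (-0.62 ± 0.081) and Nsg1 (-0.60 ± 0.081) in WT, and Gnaz (-0.53 ± 0.068) and Lgr6 (-0.81 ± 0.10) in KO. Trem2 rose by log2 2.64 ± 0.23 in WT midbrain and 3.07 ± 0.21 in KO midbrain.

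With edgeR 249 genes passed in WT striatum (240 higher, 9 lower) and 424 in KO striatum (401 higher, 23 lower). The counts were 2414 (1699 higher, 715 lower) and 4999 (2857 higher, 2142 lower) in the midbrain, and 4034 (2326 higher, 1708 lower) and 4798 (2562 higher, 2236 lower) in the brainstem. KO groups were larger, so counts are not comparable between genotypes. In KO striatum the count was 1101 without KO PFF day 90 replicate 1, 277 without KO PFF day 90 replicate 7 and 1251 (845 higher, 406 lower) without the 4 libraries with a low length slope. It was 913 (641 higher, 272 lower) with the slope as a covariate and 218 with only the groups compared. In WT striatum it was 104 without WT PFF day 90 replicate 4, 160 without WT monomer day 90 replicate 3, 120 with only the groups compared and 381 (358 higher, 23 lower) with the slope as a covariate. In the brainstem, where more genes rose than fell, the slope covariate turned that balance, with 3356 higher and 3647 lower of 7003 in WT and 3678 and 4031 of 7709 in KO. The fit without the 3 low-slope libraries gave 6262 in WT, 3036 higher and 3226 lower. The lists that passed with an estimated correlation in both genotypes of all 3 regions were disease-associated microglia, homeostatic microglia, complement and reactive astrocyte. In that test no list call of either genotype held in the striatum or brainstem with the length slope as a covariate. Without the low-slope libraries 3 of 7 held in WT striatum, 1 of 7 in KO striatum and 0 in the brainstem. Interferon genes had medians of 1.99 in WT and 1.76 in KO striatum, 2.61 and 2.52 in the midbrain, and 3.13 and 2.98 in the brainstem. Disease-associated microglia genes had medians of 0.95 and 1.11, 2.70 and 3.06, and 3.0 and 2.85 in the same order. In KO midbrain the interferon list had an adjusted p = 0.0564 with an estimated correlation. Dopaminergic markers had a median of -0.27 in WT midbrain (adjusted p = 0.598 with an estimated correlation) and -0.44 in KO midbrain (adjusted p = 0.335 with an estimated correlation). In KO Th was at -0.64 ± 0.14 and Ddc, the enzyme after it, at -0.70 ± 0.17.

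The WT and KO changes, which share no libraries, were correlated across genes. Pearson's r was 0.557 in the striatum, 0.825 in the midbrain and 0.886 in the brainstem, and Spearman's rho 0.452, 0.641 and 0.773. Genes are not independent replicates, and Gpnmb was left out. Pearson's r was 0.144, 0.251 and 0.362 with no low-count filter, and 0.638, 0.904 and 0.957 over genes above the median abundance. Of the genes called in WT, 245 of 248 had the same sign in KO in the striatum (98.8%), 2398 of 2413 in the midbrain (99.4%) and 4017 of 4033 in the brainstem (99.6%). Genes called in both numbered 213, 2209 and 3317, none with opposite signs. Independent lists of these sizes would share 5.6, 631.3 and 1012.2. The slope of KO on WT over genes called in either was 1.022, 1.064 and 0.913.

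**Figure D3:**
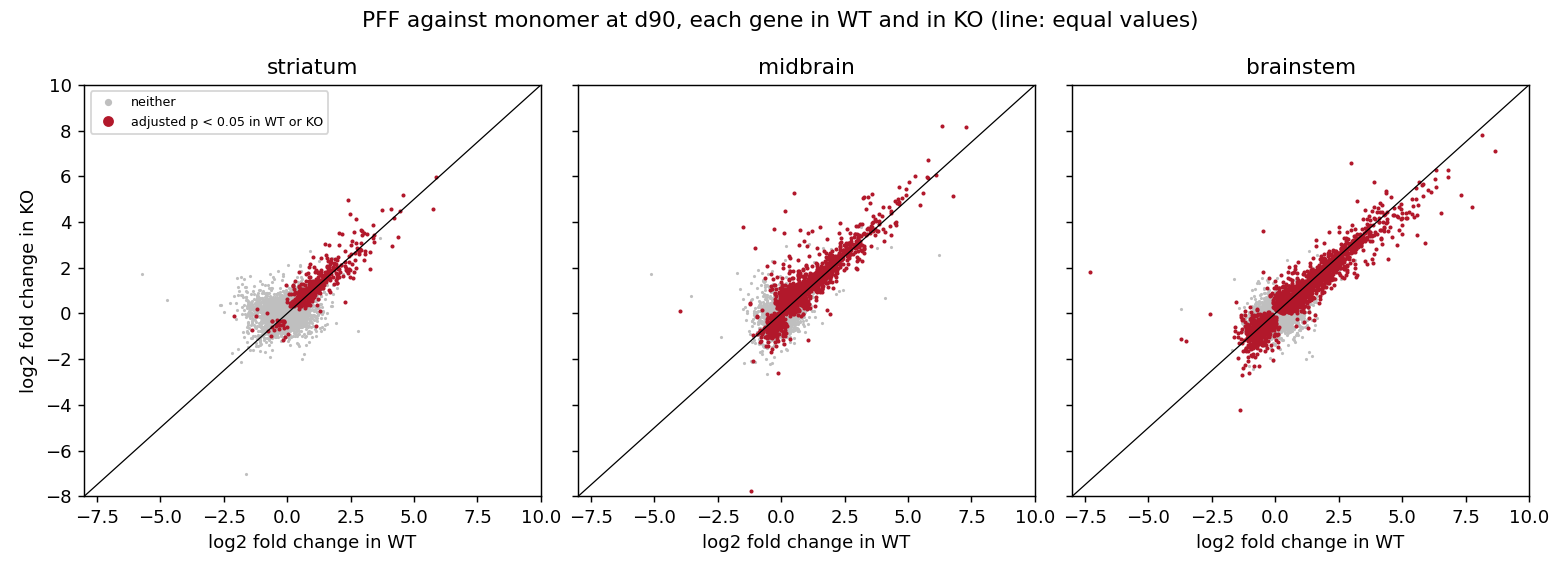
Log2 fold change of each gene after PFF against monomer at day 90 in WT (horizontal axis) and KO (vertical axis), by region; red points passed in either genotype, grey points in neither, and the line marks equal values. Most called genes lie near the line.

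The interaction tests whether the response itself differed between genotypes, and no single gene passed it in any region. The KO response minus the WT response was log2 1.57 ± 0.78 for C3 in the striatum, 0.42 ± 0.29 for Trem2 in the midbrain and -0.88 ± 0.61 for Timp1 in the brainstem, none past the threshold. With edgeR 0 genes passed in the striatum, midbrain and brainstem, with 343, 552 and 233 at an unadjusted p under 0.05, and DESeq2 called 1, 0 and 0. On simulated data the same test recovered 38%, 78% and 44% of genes given a 2-fold interaction, and 88%, 88% and 86% at 4-fold, in that order of regions. Of the lists, those that held with an estimated correlation were cholinergic and monoaminergic neurons in the midbrain (median -0.99, adjusted p = 0.0271) and the melanosome and MITF family, which does not include Gpnmb, in the brainstem (median -0.22, adjusted p = 0.0451). For the former Phox2a (-1.92 ± 0.57), Maoa (-0.20 ± 0.078), Fev (-1.23 ± 0.56) and Slc5a7 (-0.56 ± 0.28) had the smallest p, and for the latter Rab38 (-0.53 ± 0.36), Tfeb (-0.27 ± 0.19), Dct (-0.56 ± 0.40) and Pmel (-0.33 ± 0.28). Neither list had a member past the threshold, over all genes or adjusted over the list alone. With an estimated correlation the midbrain list had adjusted p = 0.0303 with the length slope and 0.0509 with the dissection scores as covariates. The brainstem call was lost with the slope (adjusted p = 0.0869), the dissection scores (0.134) and without the low-slope libraries (0.316).

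The other lists called for the interaction lost that call with an estimated correlation, and each is given with its median and that adjusted p. In the striatum these were choroid plexus (1.60, adjusted p = 0.192), ependymal (1.23, adjusted p = 0.0747), thalamic (1.21, adjusted p = 0.24) and cortical neuron genes (-0.48, adjusted p = 0.234). Also called were myelinating oligodendrocytes (0.30, adjusted p = 0.442), reactive astrocytes (0.30, adjusted p = 0.567), border-associated macrophages (-0.26, adjusted p = 0.142) and heat shock proteins (0.25, adjusted p = 0.25). Complement (0.22, adjusted p = 0.442), mural (-0.21, adjusted p = 0.17), striatal projection neuron (0.17, adjusted p = 0.567), endothelial (-0.14, adjusted p = 0.19) and lysosome genes (0.11, adjusted p = 0.475) completed them. In the midbrain they were choroid plexus (1.69, adjusted p = 0.572), immediate early (0.90, adjusted p = 0.553), and hindbrain Hox genes (-0.47, adjusted p = 0.335; -0.34 without KO PFF day 90 replicate 5), together with dopaminergic (-0.19, adjusted p = 0.393), striatal projection neuron (0.13, adjusted p = 0.189) and homeostatic microglia genes (0.13, adjusted p = 0.657). In the brainstem they were cerebellar neuron (0.98, adjusted p = 0.294), choroid plexus (-0.81, adjusted p = 0.75), Hox (-0.47, adjusted p = 0.0544; -0.33 without KO PFF day 90 replicate 5) and dopaminergic genes (0.22, adjusted p = 0.313). Also called were MHC class I (-0.21, adjusted p = 0.728), reactive astrocyte (-0.21, adjusted p = 0.543), myelinating oligodendrocyte (-0.16, adjusted p = 0.479), heat shock (0.14, adjusted p = 0.371) and pan-neuronal genes (0.12, adjusted p = 0.384). No member of any of these lists passed over all genes.

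The genotype-averaged PFF response was compared between regions in one fit of all libraries, treated as independent. Group sizes and sexes match between regions, which may share animals. Brackets give the median difference over all tested genes of a list. The rise was larger in the brainstem than in the striatum for 15 of 18 disease-associated microglia genes (log2 1.44), 15 of 16 homeostatic microglia genes (1.16), 18 of 21 interferon genes (1.10), and 8 of 14 reactive astrocyte genes (1.12). The same held for 6 of 11 complement genes (1.23), 9 of 11 MHC class I genes (0.87) and 12 of 19 lysosome genes (0.39). The fall was larger there for 9 of 14 pan-neuronal genes (-0.34). Between midbrain and striatum, 11 disease-associated microglia genes (1.23), 9 homeostatic microglia genes (0.65), 5 complement genes (0.79) and 6 lysosome genes (0.24) rose more in the midbrain. So did 2 reactive astrocyte genes (0.47), 2 MHC class I genes (0.66) and 1 interferon gene (0.42), and 3 pan-neuronal genes fell more (-0.26). Between brainstem and midbrain, 6 reactive astrocyte genes (0.70), 5 homeostatic microglia genes (0.44; 3 with RLE) and 2 interferon genes (0.56) rose more in the brainstem. So did 1 disease-associated microglia gene (0.31) and 1 lysosome gene (0.21), with no complement, MHC class I or pan-neuronal gene past the threshold.

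The time comparison sets PFF day 90 against PFF day 60, averaged over genotypes (12 libraries each per region). In the midbrain the water channel gene Aqp4 (1.78-fold, log2 0.83 ± 0.072), Timp1 (3.46-fold, log2 1.79 ± 0.16), and Sgpl1 (1.37-fold, log2 0.46 ± 0.042) were higher at day 90. So were the phagocytic receptor gene Axl (1.58-fold, log2 0.66 ± 0.061) and Tgfb1 (1.78-fold, log2 0.83 ± 0.079). Gpam (log2 0.45 ± 0.043), Cnn3 (0.59 ± 0.057) and Plek (0.95 ± 0.091) followed. Lower at day 90 were Atp1b1 (-0.24 ± 0.026), Nap1l2 (-0.30 ± 0.033), Dync1i1 (-0.24 ± 0.028), the calcium sensor gene Vsnl1 (-0.28 ± 0.032), Nkrf (-0.30 ± 0.036), Tuba4a (-0.27 ± 0.033), Snap25 (-0.25 ± 0.031) and Rtn1 (-0.19 ± 0.024). With edgeR 3871 genes passed, 2345 higher and 1526 lower. The split was 2091 and 1954 with RLE, 2138 and 2074 with DESeq2, and 1906 and 1879 in a fit of only the groups compared.

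In the brainstem S1pr3, a sphingosine phosphate receptor of reactive astrocytes (3.42-fold, log2 1.78 ± 0.13), Tgm1 (10.7-fold, log2 3.42 ± 0.27), and Tent5c (3-fold, log2 1.58 ± 0.12) were higher at day 90. So were the cytokine feedback gene Socs3 (3.65-fold, log2 1.87 ± 0.15) and the lysosomal enzyme gene Naglu (2.03-fold, log2 1.02 ± 0.081). Serpina3n (log2 2.27 ± 0.18), Itgb5 (1.0 ± 0.080) and St14 (1.73 ± 0.14) followed. Slc17a6, a vesicular glutamate transporter (-0.39 ± 0.046), St8sia3 (-0.37 ± 0.046), Armh4 (-0.38 ± 0.049), the potassium channel gene Kcnc2 (-0.30 ± 0.039), Lrfn5 (-0.35 ± 0.045), Clvs2 (-0.41 ± 0.054), Rragb (-0.30 ± 0.040) and the synaptic vesicle gene Sv2b (-0.51 ± 0.067) were lower. With edgeR 3990 genes passed, 2371 higher and 1619 lower. The count was 7156 (3776 higher, 3380 lower) with the length slope as a covariate, 6203 (3098 higher, 3105 lower) without the 3 low-slope libraries, and 4398 (2192 higher, 2206 lower) with only the groups compared. In the striatum 0 genes passed with edgeR, 720 had an unadjusted p under 0.05, and DESeq2 called 1.

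By lists, disease-associated microglia genes rose from day 60 to day 90 in 18 of 18 cases in the midbrain (median 1.21) and 18 of 18 in the brainstem (median 1.46). Homeostatic microglia genes had 15 of 16 higher (median 0.59) and 15 of 16 (1.01) in these regions, complement genes 10 of 11 (1.14) and 10 of 11 (1.68), and reactive astrocyte genes 13 of 13 (1.01) and 14 of 14 (1.63). Pan-neuronal genes had 11 of 14 lower (median -0.22) and 13 of 14 (-0.33). In that order of lists the counts adjusted over the list alone were 18, 16, 10, 13 and 11 in the midbrain and 18, 15, 10, 14 and 13 in the brainstem. These lists held with an estimated correlation in both regions, at adjusted p up to 0.0414. Of the 6 brainstem lists called in that test 0 held with the length slope as a covariate (adjusted p 0.0847 to 0.163) or without the low-slope libraries (0.0746 to 0.155), while all 6 passed with the preset correlation and with fry. In the midbrain 5 of 6 held with the slope, and general astrocyte genes did not (adjusted p = 0.0501). General astrocyte genes held in the midbrain (9 of 12 higher, 10 adjusted over the list alone, median 0.23) and not in the brainstem (8 of 12 higher, 8 adjusted over the list alone, median 0.24, adjusted p = 0.0544 with an estimated correlation). Lysosome genes held in the brainstem (14 higher and 1 lower of 19, 14 and 1 adjusted over the list alone, median 0.46) and not in the midbrain (14 higher and 0 lower of 19, 15 and 1 adjusted over the list alone, median 0.31, adjusted p = 0.0638 with an estimated correlation). In the striatum disease-associated microglia (median 0.47), homeostatic microglia (0.18), complement (0.46), reactive astrocyte (0.61), interferon (0.53) and border-associated macrophage genes (0.33) held with an estimated correlation, at adjusted p up to 0.0238. None of these 6 held in that test with the length slope (adjusted p 0.0634 to 0.0834) or the dissection scores (0.115 to 0.185) as covariates, or without the low-slope libraries (0.0638 to 0.127). Of these lists 12, 0, 8, 9, 17 and 0 genes passed adjusted over the list alone, and 0 over all genes. Among them were Cd68 (0.49 ± 0.14), C1qb (0.63 ± 0.19), Osmr (0.60 ± 0.16) and Mx1 (0.98 ± 0.30).

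The remaining lists called for time lost that call with an estimated correlation, and each is given with its median and that adjusted p. In the midbrain they were interferon (0.60, adjusted p = 0.214), MHC class I (0.76, adjusted p = 0.0948), MHC class II (0.48, adjusted p = 0.475), dopaminergic (-0.23, adjusted p = 0.547), border-associated macrophage (0.38, adjusted p = 0.407), Parkinson disease (-0.097, adjusted p = 0.0678) and hindbrain Hox genes (-0.28, adjusted p = 0.572). Interferon genes there had 21 of 21 higher, 21 adjusted over the list alone, and dopaminergic markers 1 higher and 4 lower of 14, 1 and 6 adjusted over the list alone. In the brainstem they were interferon (1.11, adjusted p = 0.0573), MHC class I (1.05, adjusted p = 0.0544), T cell (0.61, adjusted p = 0.471), border-associated macrophage (0.31, adjusted p = 0.344), Parkinson disease (-0.19, adjusted p = 0.089), cholinergic and monoaminergic (-0.43, adjusted p = 0.294), cortical (-0.25, adjusted p = 0.194) and striatal projection neuron genes (-0.17, adjusted p = 0.16). All 21 interferon and all 11 MHC class I genes were higher there at day 90, with 21 and 11 adjusted over the list alone. In the striatum they were erythrocyte (2.05, adjusted p = 0.161), MHC class I (0.36, adjusted p = 0.1), lysosome (0.12, adjusted p = 0.1), cerebellar neuron (-0.57, adjusted p = 0.418; -0.09 without KO PFF day 60 replicate 2), striatal projection neuron (-0.096, adjusted p = 0.379), pan-neuronal (-0.051, adjusted p = 0.199) and heat shock genes (-0.14, adjusted p = 0.433). None of the 4 tested erythrocyte genes passed over all genes, and 4 did adjusted over the list alone.

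The genotype comparison sets KO against WT, averaged over monomer day 90, PFF day 60 and PFF day 90 (18 KO and 17 WT libraries per region). Besides Gpnmb, a long noncoding RNA on the same chromosome was lower in KO. Gm7932 (GRCm38 chromosome 6, 48860329 to 48866083), named here after its values were seen, changed by log2 -1.07 ± 0.15 in the striatum (adjusted p = 0.000224), -0.48 ± 0.11 in the midbrain (adjusted p = 0.144) and -0.34 ± 0.12 in the brainstem (adjusted p = 0.994). In the midbrain Cacna2d4, a calcium channel subunit gene (chromosome 6, 119236526 to 119352407; log2 -0.59 ± 0.10, adjusted p = 0.0201) was lower. So were Prob1 (chromosome 18; -0.23 ± 0.041, adjusted p = 0.0201) and Pkp4, a plakophilin gene (chromosome 2; -0.15 ± 0.027, adjusted p = 0.0222). With edgeR 2 genes passed in the striatum, 4 in the midbrain and 1 in the brainstem, Gpnmb included, with 186, 1496 and 251 at an unadjusted p under 0.05. In the midbrain the count was 27 (4 higher, 23 lower) with DESeq2 and 1 with the length slope or the dissection scores as covariates. Leaving out 1 library gave 1 without KO PFF day 60 replicates 1 or 3 or WT monomer day 90 replicate 2, and 2 without WT PFF day 90 replicate 2. It gave 7 without KO PFF day 60 replicate 2, 10 and 12 without WT PFF day 60 replicates 4 and 7, 14 without WT monomer day 90 replicate 5, and 17 without KO monomer day 90 replicate 6.

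Within single conditions Gpnmb was the gene called in every region. In monomer day 90 (6 KO, 5 WT) and PFF day 90 (7 KO, 5 WT) it was the single gene past the threshold in the edgeR fit of each region. In the striatum, midbrain and brainstem 589, 659 and 205 genes had an unadjusted p under 0.05 after monomer, and 274, 962 and 271 at PFF day 90. In the midbrain DESeq2 called 4 after monomer, and in the brainstem 2 passed at PFF day 90 with the length slope as a covariate and without WT PFF day 90 replicate 2. At PFF day 60 (5 KO, 7 WT) Cbln3, a cerebellar granule cell gene, was higher in KO striatum by log2 5.69 ± 1.04 (adjusted p = 0.03). The change was 0.005 without KO PFF day 60 replicate 2 (adjusted p = 0.997), so the fold rests on that library, and the call held in 4 of 12 fits that left out 1 library. It turned to -0.43 with the dissection scores as covariates, of which it is a member. The library KO PFF day 60 replicate 2 had a cerebellar neuron score of 3.45, the highest of the striatal libraries. Gm7932 was also lower there (-1.49 ± 0.26, adjusted p = 0.0188), for 3 genes in all, against 15 with DESeq2, 5 without the sex term, and 1 with the dissection scores, without the low-slope libraries, with no low-count filter or with only the groups compared. The count was 1 without WT PFF day 60 replicates 1, 2, 4 or 6 or KO PFF day 60 replicate 2, and 7 without KO PFF day 60 replicates 1, 4 or 5. In the brainstem Trip6, an adhesion adaptor gene (chromosome 5, 137309654 to 137314404), changed by log2 -0.61 ± 0.11 (adjusted p = 0.0313), and 4794 genes had an unadjusted p under 0.05. Trip6 did not pass with the length slope as a covariate, where 835 genes had an unadjusted p under 0.05. Nor did it pass with the dissection scores, no low-count filter, only the groups compared, or without WT PFF day 60 replicates 1, 4, 5 or 6 or KO PFF day 60 replicates 2, 4 or 5. In the midbrain Gpnmb alone passed, with 918 genes at an unadjusted p under 0.05.

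Of the lists, myelinating oligodendrocyte genes passed camera as lower in KO in all 3 regions. In the midbrain their median was -0.19 and the call held with an estimated correlation (adjusted p = 0.0246), with 0 of 14 genes past the threshold over all genes and 13 adjusted over the list alone. Mbp, which encodes myelin basic protein (-0.20 ± 0.043), Cnp (-0.18 ± 0.042) and Mog (-0.21 ± 0.053) were among those with the smallest p. In the striatum (median -0.21, adjusted p = 0.0657) and brainstem (median -0.095, adjusted p = 0.126) that call was lost. The adjusted p beside the following medians is that with an estimated correlation. Cerebellar neuron genes passed as higher in KO striatum (median 0.50, adjusted p = 0.389; 0 of 7 higher, 2 adjusted over the list alone), midbrain (median 0.98, adjusted p = 0.36) and brainstem (median 0.47, adjusted p = 0.247). The striatal median was 0.07 without KO PFF day 60 replicate 2, so it rests on that library. Interferon genes in the midbrain (median -0.12, adjusted p = 0.688) and brainstem (median -0.10, adjusted p = 0.62), homeostatic microglia genes in the midbrain (median -0.085, adjusted p = 0.53) and MHC class I genes in the brainstem (median -0.068, adjusted p = 0.62) passed as lower with the preset correlation. So did lysosome genes in the midbrain (-0.052, adjusted p = 0.611) and brainstem (-0.033, adjusted p = 0.543).

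Leaving out 1 library changed the sign of 1 of 7 striatal genotype lists. The other lists passed with the preset correlation only, and each is given with its median and adjusted p with an estimated correlation. In the striatum they were choroid plexus (-0.54, adjusted p = 0.192), border-associated macrophage (0.16, adjusted p = 0.234), cortical neuron (-0.13, adjusted p = 0.556), cholinergic and monoaminergic (0.12, adjusted p = 0.109) and striatal projection neuron genes (-0.046, adjusted p = 0.653). In the midbrain they were thalamic (-0.42, adjusted p = 0.393), dopaminergic (-0.12, adjusted p = 0.415), cholinergic and monoaminergic (0.11, adjusted p = 0.553) and oligodendrocyte precursor genes (-0.063, adjusted p = 0.239). In the brainstem they were Hox genes (0.10, adjusted p = 0.668), the unfolded protein and integrated stress response (-0.055, adjusted p = 0.52) and the chromosome 6 neighbours of Gpnmb (-0.035, adjusted p = 0.307). No member of any of these lists passed over all genes.

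**Figure D4:**
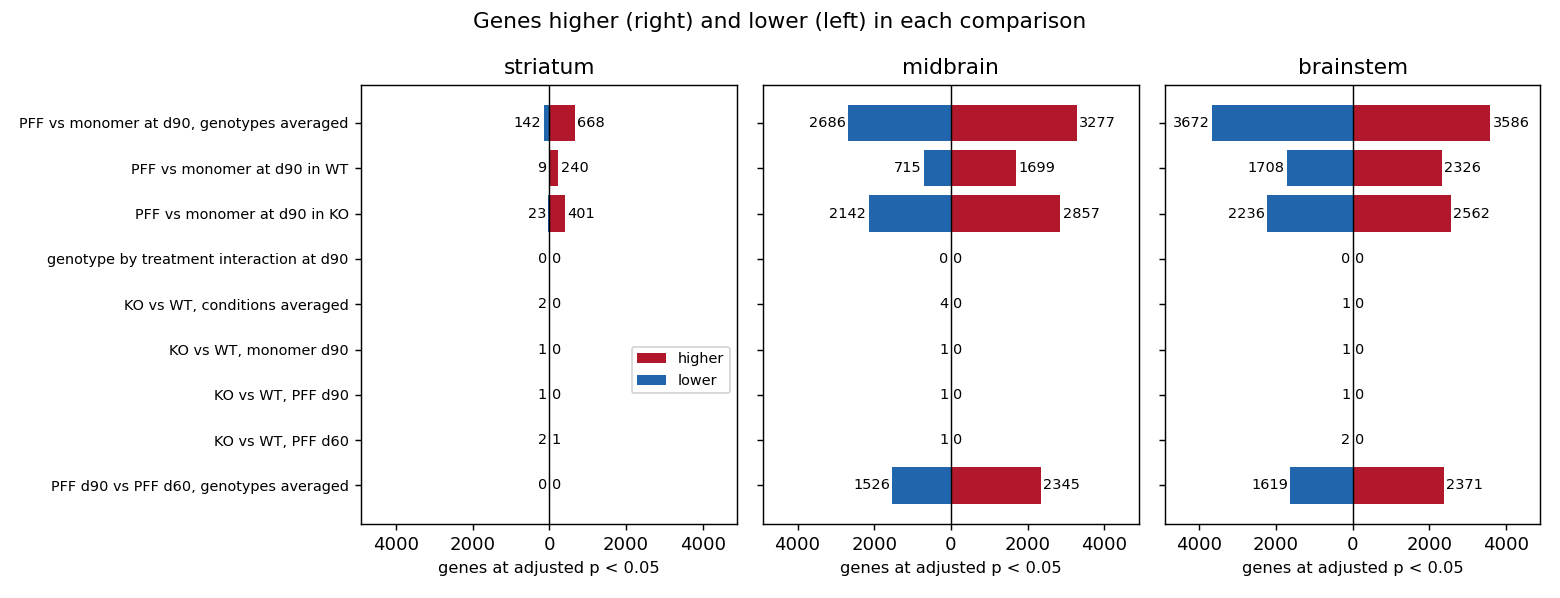
Number of genes higher (right, red) and lower (left, blue) at an edgeR adjusted p under 0.05 in each comparison (vertical axis) and region. PFF comparisons in the midbrain and brainstem reach 5963 and 7258 genes and genotype comparisons at most 4.

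Libraries differed in ways the groups do not explain. The length slope, the change of a library's log2 abundance per doubling of gene exon length relative to the regional mean, was below -0.25 in 4 striatal libraries. These were KO PFF day 90 replicate 1, KO monomer day 90 replicate 1, WT monomer day 90 replicate 1 and WT PFF day 60 replicate 6. In the brainstem it was below that limit in WT PFF day 60 replicates 5 and 6 and KO monomer day 90 replicate 5, and in no midbrain library. The limit was set after the values were seen. Choroid plexus genes scored from -4.19 to 2.43 on the log2 scale between brainstem libraries and from -0.78 to 3.40 between midbrain libraries, and cerebellar neuron genes from -1.0 to 3.45 between striatal libraries.

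**Figure D5:**
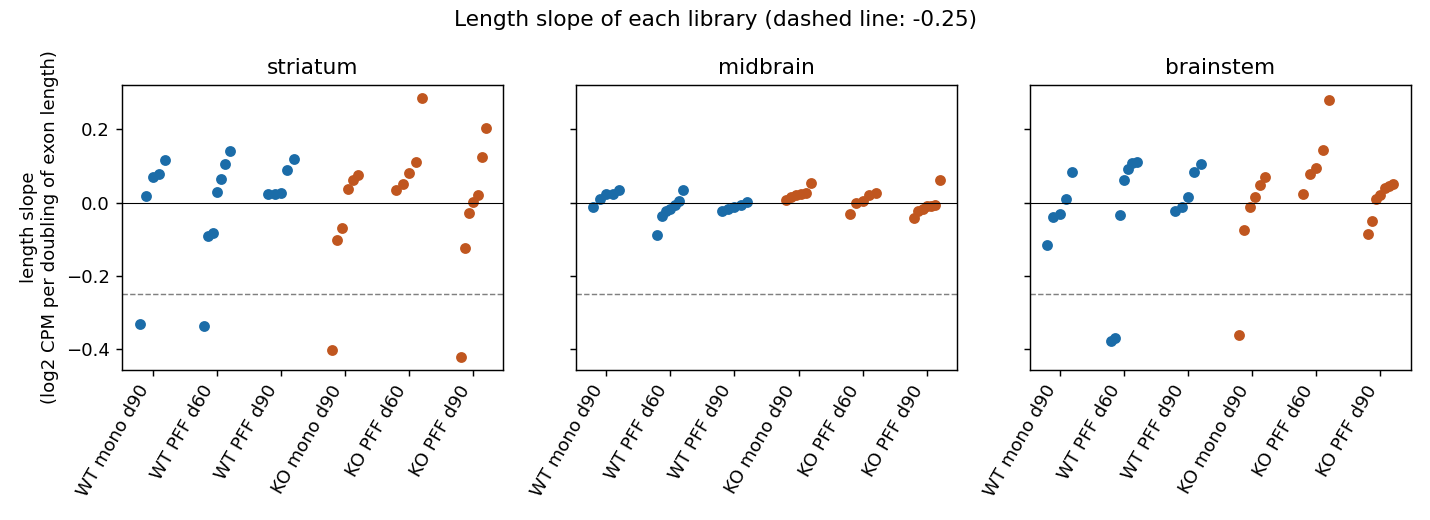
Length slope of each library (points; log2 CPM per doubling of exon length) by region and group, with WT in blue and KO in orange; the dashed line marks -0.25. Below it lie 4 striatal and 3 brainstem libraries and none of the midbrain.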

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

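In this part the dilution tests of the pan-neuronal score, the limit on the length slope, and the fits that use the length slope, the dissection scores or the thalamic score were tests chosen only after results were seen.

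The size of the PFF response differed between regions by a test of the difference itself. Of 359 named genes, 131 responded differently in the brainstem than in the striatum (104 with a larger and 27 with a smaller change), and 69 in the midbrain than in the striatum (59 and 10). Between brainstem and midbrain 23 differed (17 and 6). The rule that named these genes picked strong changes within single regions or members of the lists, which favours such differences. The direction counts are of signed changes, so a deeper fall counts as smaller.

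The PFF response of 2 lists passed the interaction test between genotypes with an estimated correlation. That adjustment was shared with the PFF and time comparisons, whose many calls loosen it. Cholinergic and monoaminergic neuron genes in the midbrain had a median difference of -0.99, and the melanosome and MITF family in the brainstem one of -0.22, both lower in KO. No gene of either list passed on its own, and the medians were -0.50 without midbrain WT PFF day 90 replicate 2 and -0.13 without brainstem KO monomer day 90 replicate 5. The brainstem call was lost with the length slope (adjusted p = 0.0869) or the dissection scores (0.134) as covariates and without the low-slope libraries (0.316), and the midbrain call with the dissection scores (0.0509). Hindbrain Hox genes had a median of -0.47 in the same midbrain comparison (adjusted p = 0.335 with an estimated correlation; -0.34 without KO PFF day 90 replicate 5, the library with the lowest Hox score of its group), so the amount of hindbrain tissue in a library was not separated from genotype there.

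Over 81 combinations of a group of 5 to 7 libraries and a measure, 8 had 1 library that stood apart from the others. Chance separates about 1 in 20 such groups, and the combinations are not independent because the same libraries recur in them. On the length slope these were brainstem KO monomer day 90 replicate 5 (-0.363, others -0.074 to 0.069), striatum KO monomer day 90 replicate 1 (-0.403, others -0.102 to 0.075) and striatum WT monomer day 90 replicate 1 (-0.331, others 0.017 to 0.116). Midbrain KO PFF day 90 replicate 5 stood above its group (0.061, others -0.041 to -0.007). The disease-associated microglia score was higher than in the rest of the group in midbrain WT monomer day 90 replicate 3 (-1.23, others -1.57 to -1.50) and in striatum KO monomer day 90 replicate 1 (-0.393, others -1.02 to -0.898). Brainstem WT PFF day 60 replicate 1 had a low pan-neuronal score (-0.268, others 0.082 to 0.158), and brainstem WT PFF day 60 replicate 3 held Gpnmb at 61.0 CPM (others 7.5 to 21.3). No cause of these single values was tested.

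The lower pan-neuronal list under PFF was weighed in the midbrain and brainstem. The score fell by 0.316 ± 0.023 (SE) in the midbrain and by 0.421 ± 0.047 in the brainstem, and with the length slope as a covariate it stood at -0.333 ± 0.025 and -0.413 ± 0.048, which argues against the length slope as its cause. Dilution by the RNA of cells that rose would lower oligodendrocyte genes alike, but their score exceeded the pan-neuronal score by 0.326 ± 0.062 and 0.448 ± 0.093, which argues against dilution as the whole cause. With the dissection scores as covariates the change was -0.317 ± 0.024 and -0.475 ± 0.057. Fewer neurons, or less of these transcripts per neuron, stay open as hypotheses and may both apply, and library depth was not tested as a cause.

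At PFF day 60 in the brainstem 4794 of 19119 genes had an unadjusted p under 0.05 between KO and WT, although 2 passed after adjustment. WT PFF day 60 replicates 5 and 6 had a length slope below -0.25, and the number was 1158 without the low-slope libraries and 835 with the slope as a covariate. Both values are in line with a difference of length coverage between libraries, not of genotype, as the source of most of that excess. Chance could not be excluded, since the highest of the other splits of the same libraries gave 8763 such genes and, after adjustment and without Gpnmb, 5867 against the real 1. A split that calls so many genes points to a structure of the samples, and a genotype difference at this day, which the design names, stays open.

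The lower myelinating oligodendrocyte list in KO was weighed against dissection. With the choroid plexus, cerebellar and cortical scores as covariates the KO minus WT score changed from -0.203 ± 0.109 to -0.227 ± 0.096 in the striatum and from -0.195 ± 0.046 to -0.111 ± 0.036 in the midbrain, which argues against these tissues as its whole cause there, although the striatal value before the correction was itself within 2 SE of 0. In the brainstem it changed from -0.101 ± 0.054 to -0.065 ± 0.052. Both values lie within 2 SE of 0, so no difference was established there, and dissection and genotype cannot be told apart. Thalamic neuron genes, called as lower in KO midbrain with the preset correlation only (median -0.42), were not among those scores, and with the thalamic score as the covariate the values were -0.232 ± 0.065, -0.167 ± 0.047 and -0.102 ± 0.050 in striatum, midbrain and brainstem, the last barely past 2 SE, which argues against thalamic tissue as the whole cause. White matter has no separate marker in the lists, so its share stays open, and an effect of genotype on myelin transcripts may remain.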

How the results depend on the processing

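Fits without the low-slope libraries, with the length slope as a covariate and with the dissection scores as covariates were tests chosen only after the data were seen, and the other alternatives were chosen earlier.

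Of counts, correlations and list results, RLE left 59 of 60 within the limit of 1.5 times, DESeq2 22 of 27, no low-count filter 25 of 30, no sex term 29 of 30 and a fit of only the groups compared 23 of 27. The dissection scores left 27 of 30, the length slope covariate 21 of 30 and the fit without the low-slope libraries 14 of 20. Of 919 values of named genes past the threshold, the same direction and side held for 914 with DESeq2, 909 with RLE, 905 with no sex term, 892 with the length slope, 842 with no filter and 833 with the dissection scores. They held for 853 of 905 with only the groups compared and for 536 of 543 without the low-slope libraries. DESeq2 gave no adjusted p for Egr2 in 3 midbrain comparisons.

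With the length slope as a covariate the PFF count was 2110 in the striatum, 381 in WT and 913 in KO striatum, and 7003 in WT and 7709 in KO brainstem. The time count of the brainstem was 7156. Without the low-slope libraries the counts were 2295 for the striatum, 1251 for KO striatum, 6262 for WT brainstem and 6203 for time in the brainstem. These fits take out or leave out the length trend and their counts rose, whereas of KO against WT the count at PFF day 60 was 1 in striatum and 1 in brainstem without those libraries. With the slope covariate it was 1 there in the brainstem, 1 for the midbrain average and 2 at PFF day 90 in the brainstem. A fit of only the groups compared, which estimates the spread from fewer libraries, gave 120 in WT and 218 in KO striatum, and 1 for KO against WT at PFF day 60 in striatum and in brainstem.

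DESeq2 called 1 gene for the interaction and 1 for time in the striatum, 15 for KO against WT at PFF day 60 in the striatum, and 27 for the average and 4 for monomer in the midbrain. For KO against WT at PFF day 60, no low-count filter gave 1 in striatum and 1 in brainstem, no sex term 5 in striatum, and the dissection scores 1 in striatum and 1 in brainstem, with 1 for the midbrain average. The cause was not tested for these. Cbln3 in KO striatum at PFF day 60 turned from 5.69 to -0.43 with the dissection scores, which include Cbln3. The WT and KO changes correlated at 0.144, 0.251 and 0.362 in striatum, midbrain and brainstem with no filter, which adds genes with few reads. List calls over 6 comparisons fell from 75, 79 and 75 to 28, 29 and 29 with an estimated correlation, which treats members that vary together as fewer genes, and were 34 in the striatum with fry, which asks another question. With that estimated correlation, the length slope as a covariate gave 0 list calls in striatum, 30 in midbrain and 0 in brainstem, the fit without the low-slope libraries 6 in striatum and 0 in brainstem, and the dissection scores 26, 38 and 24. The cause was not tested. RLE gave 3 in place of 5 homeostatic microglia genes with a larger response in brainstem than in midbrain, and the cause was not tested.

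Leaving out 1 library at a time, the striatal PFF count ran from 579 (without WT PFF day 90 replicate 4) to 1990 (without KO PFF day 90 replicate 1). In KO striatum it ran from 277 (without KO PFF day 90 replicate 7) to 1101 (without KO PFF day 90 replicate 1), and in WT striatum from 104 (without WT PFF day 90 replicate 4) to 275 (without WT PFF day 90 replicate 5). For KO against WT at PFF day 60 it ran from 1 to 7 in the striatum and from 1 to 2 in the brainstem, and for the midbrain average from 1 to 17, with the libraries named above. At PFF day 90 in the brainstem it ran from 1 to 2 (without WT PFF day 90 replicate 2). The other counts stayed within 1.5 times, and no named gene past the threshold changed sign in any of these fits. Calls of named genes lost in at least 1 such fit for PFF were 8 of 59, 8 of 114 and 14 of 121 with genotypes averaged in striatum, midbrain and brainstem, 16 of 36, 9 of 67 and 26 of 95 in WT, and 4 of 36, 14 of 100 and 8 of 87 in KO. For time they were 12 of 88 in midbrain and 10 of 99 in brainstem, and for KO against WT 3 of 4 in the midbrain average and 1 of 2 at PFF day 60 in striatum and in brainstem. List medians without each library were added after the data were seen. Of lists called with the preset correlation, in striatum, midbrain and brainstem, 11 of 13, 6 of 7 and 8 of 10 moved over 1.5 times in at least 1 fit for the interaction, 5 of 7, 4 of 9 and 6 of 8 for averaged KO against WT (1 with a changed sign), 5 of 13, 1 of 14 and 1 of 15 for time, and 2 of 13, 0 of 17 and 0 of 14 for averaged PFF. For PFF in WT 5 of 16, 1 of 15 and 0 of 15 did, and in KO 3 of 13, 0 of 17 and 0 of 13.

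Of the 4 comparisons simulated the interaction was recovered least, with 2%, 32% and 6% of genes changed 1.3-fold in striatum, midbrain and brainstem. No simulation varied depth or replicate number. In KO, Gpnmb rested on 14, 9 and 3 reads, so its level there is known only as an interval.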

Other observations

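In this part the exchanges of treatment between libraries, the omission of Gpnmb from the exchanges of genotype, and the tests of 3 further gene lists were tests chosen only after results were seen. The lists were written after the PFF results, so their PFF values describe these and do not test them.

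Genes of cholesterol biosynthesis and uptake were lower after PFF at day 90, with a median log2 change of -0.21 in the striatum, -0.38 in the midbrain and -0.41 in the brainstem. Of 24 genes 3, 21 and 18 passed as lower and 0 as higher, and camera with an estimated correlation gave adjusted p = 0.0398, 0.022 and 0.00909. In KO against WT its medians were -0.11, -0.099 and -0.084. With an estimated correlation the list passed in the striatum (adjusted p = 0.0075) and brainstem (0.0319), not the midbrain (0.0699). No single gene passed. No added list was tested with the length slope or dissection scores. Myelinating oligodendrocyte genes moved the same way in that comparison (medians -0.21, -0.19 and -0.095), and the lists were not separated. Cell division genes rose after PFF in the midbrain (median 0.95) and brainstem (1.56), 20 of 20 in both (adjusted p = 0.00251 with an estimated correlation in each), and in the striatum had 0 of 20 past the threshold (median 0.25, adjusted p = 0.209 with an estimated correlation). Chemokine genes, some of which led the PFF results before the list was written, rose by medians of 2.79, 4.09 and 4.27. From day 60 to day 90 cell division genes rose further, by medians of 0.62 in the midbrain (16 of 20) and 0.94 in the brainstem (19 of 20), and chemokine genes by 1.13 (9 of 11) and 1.59 (10 of 11), with adjusted p = 0.022 with an estimated correlation in each. No gene of these lists passed the interaction, and no list held there with an estimated correlation.

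Treatment, genotype or day was exchanged within a region in 50 ways each, the real one included. For PFF against monomer with genotypes averaged, chance was excluded in all 3 regions, with 810 genes against 5 in the highest other split in the striatum, 5963 against 1 in the midbrain and 7258 against 2593 in the brainstem. In WT it was excluded too, with 249 against 0, 2414 against 0 and 4034 against 3060. In KO it was excluded in the midbrain (4999 against 2124) and brainstem (4798 against 3) but not by these splits in the striatum, where the real one gave 424 genes and the highest other 3563. WT libraries, which share no sample with KO, still moved 420 of those 424 genes the same way, and 213 were called in both genotypes against 5.6 for independent lists, none with opposite signs. These values argue against chance for the KO striatal response as a set, while its count stays uncertain. The split with 3563 points to a structure of the samples, and its length slope differed between the groups by -0.212, against 0.035 in the real one. For PFF day 90 against day 60 chance was excluded in the midbrain (3871 against 3) and brainstem (3990 against 0). In the striatum the real number was 0, the lowest possible, so chance was not tested (highest other 33).

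For the interaction the real exchange gave 0 genes in each region, which no split can fall below, so the splits did not test chance. The highest other gave 0 in the striatum, 2005 in the midbrain and 2894 in the brainstem. Whether these splits kept part of the real PFF labels was not tested. For KO against WT the deleted gene follows the real labels by design, so Gpnmb was left out of the counts. Averaged over conditions, chance was then excluded for the called genes in the striatum (1 gene against 0) and midbrain (3 against 1). This covers only those genes, since at an unadjusted p under 0.05 the striatum had 186 genes against 3313 and the midbrain 1496 against 3191, and 49 and 8 of the 50 splits gave as many. The 3 midbrain genes each lost the call when 1 library was left out, and with the length slope or the dissection scores as covariates. At PFF day 60 chance was not excluded either, in the striatum (2 against 3) or brainstem (1 against 5867). In the brainstem average, the midbrain at PFF day 60, and every region after monomer and at PFF day 90, no gene besides Gpnmb passed, so the splits did not test chance there. The highest other split gave 3948 in the brainstem average and 2 in the midbrain at PFF day 60. It gave 510, 1 and 1 after monomer and 4, 1 and 4 at PFF day 90 in the striatum, midbrain and brainstem. The splits with 510, 3948 and 5867 genes point to a structure of the samples, and in them the length slope differed between the groups by 0.188, -0.135 and -0.241. It differed by 0.068 and -0.022 in the midbrain splits with 2005 and 2124 genes, and by -0.053, 0.026 and -0.002 in the brainstem ones with 3060, 2894 and 2593. The last 2 lie below the median size over the splits (0.054 and 0.027), so the length slope does not account for them.

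Gm7932 lies 176 kb from Gpnmb on chromosome 6. A segment of the chromosome that came with the modified allele from another strain was tested as a hypothesis: genes within 5 Mb of Gpnmb, with Gpnmb left out, would then hold more differences between KO and WT than the other genes. At an unadjusted p under 0.05 stood 3 of 66 near genes in the striatum (4.5%, against 1% of the others), 11 of 73 in the midbrain (15.1% against 7.8%) and 5 of 83 in the brainstem (6% against 1.3%). Exact two-sided Fisher tests gave p = 0.0279, 0.0285 and 0.00466 over these 3 comparisons, of which the last stays under 0.05 after multiplying by 3. The excess may rest on Gm7932, which prompted the tests and was kept, so a segment stays open. A regulatory effect of the deletion on its neighbours may produce the same excess, and neither the strain of the allele nor variants in the reads were analysed here. Cacna2d4, lower in KO midbrain, lies 70200 kb from Gpnmb on the same chromosome, outside that window, and changed by -0.20 ± 0.17 in the striatum and -0.42 ± 0.097 in the brainstem, neither past the threshold.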
